A study of Mus musculus with 16 samples.

How the data were processed

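T cell receptor (TCR) chains were sequenced from single cells isolated from mouse liver tumours. The tumours came from Hepa1-6 cells, a mouse hepatoma line, placed in the left liver lobe of C57BL/6 mice, and cells were taken 5 or 14 days later. The control group (CON) carried intact Matr3 alleles and the KO group floxed Matr3 alleles, both with Cre recombinase driven by the Cd4 promoter. Matr3 encodes matrin 3, a nuclear protein that binds RNA and DNA. The series holds 16 samples. Of these, 8 are TCR libraries, with 2 libraries in each of 4 groups, and these are analysed here. The 8 single-cell RNA libraries of the same groups are not analysed here. The contig tables hold receptor chains only, so the level of Matr3 was not checked in any library.

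Per the labels' protocols, tumour tissue was dissociated into single cells, which were loaded on a droplet system that captures the 5′ end of transcripts. Per the submitters' processing notes, CASAVA 1.8, Cell Ranger 3.1.0, R 4.1.2 and Seurat 4.0.0 were used, with the mouse genome build GRCm38 (mm10). Those notes give no role to each tool. The deposited tables list assembled contigs, with a barcode, a call of whether the barcode is a cell, the chain, its V and J segment names, the CDR3 sequence and a clonotype identifier. The deposited counts of UMIs and of reads per contig are whole numbers with no normalization, per the file headers. Other deposited values, such as contig length in bases, describe the contig and were not compared. All contig read numbers were even, so reads were not used as independent molecules.

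Cells were barcodes that the authors called cells, and chains were high-confidence productive contigs. The TRA and the TRB chain with the most UMIs stood for the cell. A possible doublet was a barcode with 2 or more productive TRB or 3 or more productive TRA chains, and these were kept except in an alternative. The TRAV names of the duplicated copies of the TRA locus were merged, which left 47 of 88 names. The deposited name TRBV12-2+TRBV13-2 joins a pair of segments and was kept as its own segment. Of its 734 cells, 94.3% had a CDR3 beginning CASG, against 95.2% of the TRBV13-2 cells and 0.535% of the TRBV12-2 cells. Positions of 116 of the 124 segments seen came from RefSeq genes of the same build. Cells with TRAV11 joined to TRAJ18 are called iNKT-type (invariant natural killer T), and cells with TRAV1 joined to TRAJ33 MAIT-type (mucosal-associated invariant T). These names rest on the alpha chain alone. Receptor files do not tell CD4 from CD8 T cells.

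A clonotype was a pair of TRA and TRB chains with the same V, J and CDR3 nucleotides, and an expanded clonotype held 2 or more cells. The share of cells in expanded clonotypes and in the 10 most frequent clonotypes was the mean of 1000 subsamples to 376 cells, the number of paired cells in the smallest library. The chance that 2 cells share a clonotype was the unbiased Simpson index. Hydropathy was the mean Kyte-Doolittle value of the TRB CDR3 without its 4 residues at either end. Sharing between 2 libraries was the number of TRB amino acid clonotypes found in both per 1e+06 possible pairs. These values were compared with two-sided exact permutation tests, with genotype labels permuted within day or day labels within genotype (36 relabelings, smallest p 0.0556). Within 1 day there are 6 relabelings, and the smallest p is 0.333. For sharing the smallest p is 0.111. None of these designs can reach 0.05.

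Segment use was tested on cell counts per segment with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test). The offset was the number of TRA or TRB cells of the library, so fold changes are those of shares. The 98 segments with 40 or more cells over the 8 libraries were tested, with Benjamini-Hochberg adjustment over them in each contrast and a threshold of 0.05. All 8 libraries entered each fit. The contrasts were KO against CON at day 5, at day 14 and over both days with day as a covariate, day 14 against day 5 with genotype as a covariate, and the interaction. The same test was run on 11 fixed lists, each summed and adjusted over the lists alone. In simulated data changes of 8-fold were called for 65.5% of 58 changed segments at day 5 and 73.9% of 69 at day 14. The rates were 90% of 60 for genotype over both days, 97.4% of 77 for time and 28.6% of 63 for the interaction. Each contrast had 10 data sets of 98 segments. Changes of 2-fold were called for 6.56%, 3.85%, 14.7%, 18.3% and 1.67% in the same order.

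The tests, lists, alternatives and the rule for naming segments were set before the data were examined. The rule names all segments past the threshold, up to 10 in each direction, or the 8 with the smallest p where fewer than 8 pass. For each list it names the sum and the 2 to 4 tested members with the largest absolute log2 fold change, and of clonotypes the most frequent of each library and any among the 3 most frequent of 2 or more libraries, of which there was none. Alternatives were TMM factors, DESeq2 1.42.0, no filter on low counts, each clonotype counted once, TRAV copies kept apart, chains with 2 or more UMIs, possible doublets left out, other clonotype definitions, no subsampling, TRA UMIs thinned to 4 per cell, a replicate block and leaving out each library. Others were added after seeing the data, among them the removal of iNKT-type cells from the segment tests. Python 3.11.15 and SciPy 1.17.1 were used for the other values. Binomial intervals are exact Clopper-Pearson intervals at 95% and, like the limit of 3 counts given for a count of 0, cover counting error only.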

Results

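TCR chains were read from 5908 cells in 8 libraries of dissociated tumour tissue, with 2 libraries each of CON and KO mice at day 5 and at day 14. A library held 474 to 1404 cells and 7683 to 31936 UMIs in productive chains. Cells with both a TRA and a TRB chain numbered 376 to 1189 per library, and the median was 3 to 5 UMIs for a TRA chain and 8 to 12 for a TRB chain. Possible doublets made up 1.33% to 3.92% of cells. No cell carried a productive gamma or delta chain, and no contig came from an immunoglobulin gene. Whether these libraries can capture such chains was not checked, so cells that carry them may have been present. The series asks how loss of Matr3 in T cells changes the infiltrate and its receptors at these times. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure only the spread between these libraries, which may be technical.

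Most T cells had a receptor seen in no other cell of the library at day 5, while expanded clonotypes were common at day 14. Expanded clonotypes held 5.61% ± 4.40 of paired cells at day 5 and 53.3% ± 5.12 at day 14 (SD, n = 4 each). The 10 most frequent clonotypes held 5.98% ± 2.48 at day 5 and 34.9% ± 5.90 at day 14. The chance that 2 cells drawn at random share a clonotype was 0.0460% ± 0.0479 at day 5 and 2.48% ± 0.758 at day 14. The differences between days were 47.7, 28.9 and 2.43 percentage points in that order, and all 4 libraries of day 14 lay above all 4 of day 5 in each. Each gave p = 0.0556 in the exact permutation test, the smallest this design allows, and 0.0648 after adjustment over 7 measures.

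**Figure D1:**
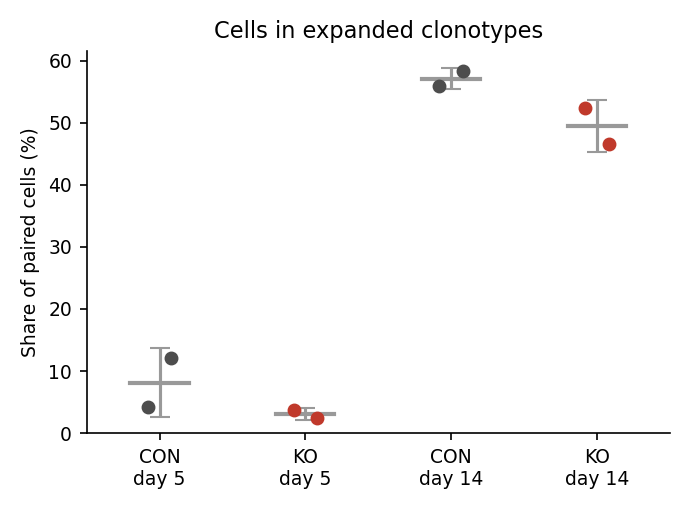
Share of paired cells that belong to clonotypes of 2 or more cells (y axis, percent) for the 4 groups (x axis), at 376 cells per library. Points are libraries, grey lines are group means and bars are the SD (n = 2), and the day 14 libraries lie between 46.5% and 58.3% while those of day 5 lie between 2.39% and 12.1%.

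Cells with the iNKT-type alpha chain, the invariant receptor by which natural killer T cells recognise lipids presented by CD1d, were common at day 5 and scarce at day 14. They made up 28.8% ± 2.10 of cells with a TRA chain at day 5 and 4.001% ± 1.231 at day 14 (SD, n = 4 each). The log2 fold change was -2.87 ± 0.28 (SE, edgeR adjusted p = 2.41e-08 over the 11 lists). Of these alpha chains 93.4% had the CDR3 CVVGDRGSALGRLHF, and 50.7% of the paired iNKT-type cells used the joint TRBV12-2+TRBV13-2 name, 14.7% TRBV13-1 and 11.3% TRBV29. MAIT-type cells were at most 1 per library, and where none was seen the count allowed a share of up to 0.243% to 0.648% of TRA cells.

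**Figure D2:**
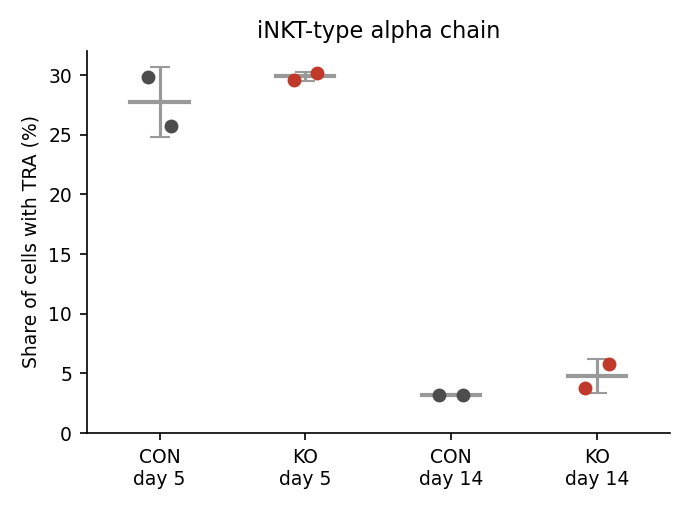
Share of cells with a TRA chain that carry TRAV11 joined to TRAJ18 (y axis, percent) for the 4 groups (x axis). Points are libraries, grey lines are group means and bars are the SD (n = 2), and the day 5 libraries lie between 25.7% and 30.2% while those of day 14 lie between 3.18% and 5.80%.

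Of 98 segments tested between the days, 3 rose and 7 fell at day 14 (DESeq2 called 12, with all 10 among them). The falls were led by the iNKT-type pair. TRAV11 (chromosome 14, 53519303 to 53519859, GRCm38, a V segment) went from 29.1% ± 1.96 to 4.16% ± 1.13 of TRA cells, with a log2 fold change of -2.82 ± 0.19 (SE, adjusted p = 4.17e-06). TRAJ18 (chromosome 14, 54200777 to 54200842, a J segment) had a log2 fold change of -2.53 ± 0.23. The TRB segments that fell were the joint TRBV12-2+TRBV13-2 name (-1.57), TRBV13-2 (-1.79), TRBV31 (-1.65), TRBJ1-5 (-1.39) and TRBJ1-3 (-1.15). The rises were TRAJ27 (chromosome 14, 54192303 to 54192361), from 2.99% ± 0.774 to 10.6% ± 4.33 of TRA cells with a log2 fold change of 1.77 ± 0.34, TRAV10 (1.60) and TRBV3 (1.20). TRBV3 (chromosome 6, 41048394 to 41048824) went from 5.76% ± 0.628 to 13.2% ± 3.31 of TRB cells. With each clonotype counted once the joint name (-0.98), TRBV13-2 (-0.98) and TRBV31 (-0.80) passed at a smaller size, while TRAV10 (0.50), TRBJ1-5 (-0.71) and TRBJ1-3 (-0.49) did not pass, nor did these 3 with no filter on low counts or with the replicate block. TRAV10 did not pass with TRAV copies kept apart (1.31), with chains of 2 or more UMIs (1.52) or without possible doublets (1.63) either, nor TRBJ1-5 with TRAV copies kept apart (-1.39). Leaving out 1 library ended the call of TRAV10 except for the day 14 KO library of replicate 2, of TRBJ1-3 except for that of replicate 1, and of TRBJ1-5 except for the day 14 CON library of replicate 1 and the day 14 KO library of replicate 2. TRBV13-2 (-1.64) and TRBV31 (-1.59) did not pass without the day 5 CON library of replicate 1, TRAJ27 (1.67) without that of replicate 2 and TRBV13-2 (-1.72) without the day 5 KO library of replicate 1, so that 5, 6 and 6 segments passed. Without iNKT-type cells, an alternative added after seeing the data, TRBV31 (-1.86) and the joint name (-1.08) passed. TRBV13-2 (-1.77) and TRBJ1-3 (-1.25) then kept their size but not the call, and TRAJ27 (1.35), TRAV10 (1.17), TRBV3 (0.88), TRBJ1-5 (-0.83) and TRAJ18 (-0.59) were smaller and did not pass.

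**Figure D3:**
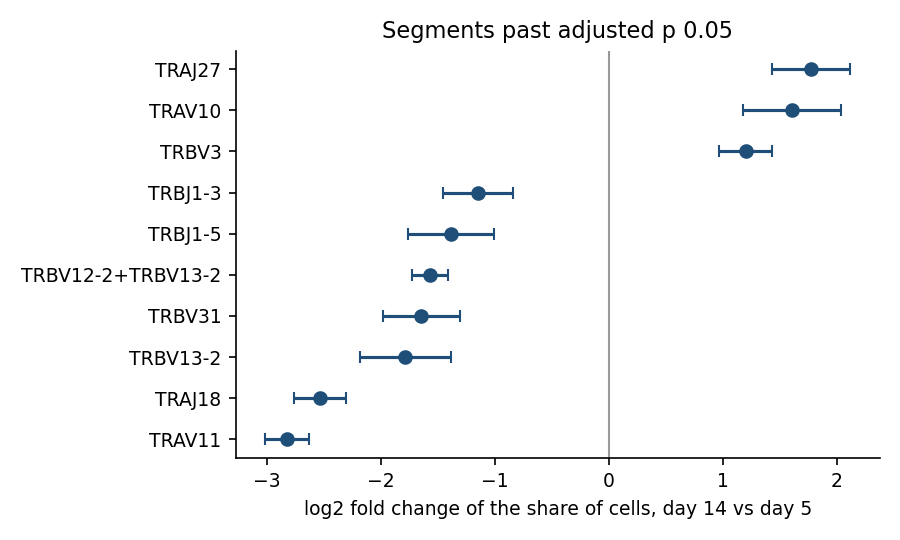
Log2 fold change of the share of cells that carry each segment, day 14 against day 5 (x axis), for the 10 segments past the threshold (y axis). Points are edgeR estimates over 8 libraries and bars are their standard errors, and they run from -2.82 for TRAV11 to 1.77 for TRAJ27.

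Of the 11 fixed lists, 2 fell between the days and none rose. These were the iNKT-type alpha chain and the V-distal J alpha list, whose members lie far from the V segments and join in late rearrangements. The V-distal list went from 45.9% ± 1.68 to 23.0% ± 10.3 of TRA cells, with a log2 fold change of -1.06 ± 0.23 (SE, edgeR adjusted p = 0.000775). Of its 10 tested members 1 fell (TRAJ18) and 9 did not pass, among them TRAJ5 (1.35) and TRAJ17 (-0.62). Without iNKT-type cells, an alternative added later, its log2 fold change was -0.35 and no list passed. The iNKT-type alpha chain could not pass there, since its cells were removed, and the V-distal list lost their TRAJ18 chains. Without the day 14 CON library of replicate 1, 4 lists passed, with TMM factors 4, and with each clonotype counted once 7. The V-proximal J alpha list (0.53, with TRAJ50 at 2.82 and TRAJ43 at 1.42), the Vbeta5 list (0.81, with TRBV12-1 at 1.37 and TRBV12-2 at -0.09), the J-distal V alpha list (0.73, with TRAV2 at 1.72) and the Jbeta2 cluster (0.02, with TRBJ2-1 at -0.50 and TRBJ2-4 at -0.33) did not pass, and none of their tested members did. The iNKT V beta list (-0.17), the MAIT V beta list (-0.12) and the Vbeta8 list (-0.06) did not pass as sums, but their shared member TRBV13-2 (-1.79) did. Of their other members, TRBV13-3 (-1.04) and TRBV13-1 (0.58), in all 3 lists, and TRBV29 (-0.83), in the iNKT V beta list, did not pass. Nor did the J-proximal V alpha list (-0.28, with TRAV16 at -0.07) or the MAIT-type alpha chain (-1.72). The iNKT V beta, MAIT V beta and Vbeta8 sums leave out the joint name, and their values depend on this: with it counted as TRBV13-2, also added later, they were -0.60, -0.63 and -0.69 and passed, as did Vbeta5 (0.81), which made 6 lists. Adjusted over the list alone, 3 of the 5 iNKT V beta members, 2 of the 4 MAIT V beta members, 2 of the 3 Vbeta8 members and 1 of the 2 Vbeta5 members passed, against 1, 1, 1 and 0 over all segments.

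On average KO libraries held a smaller share of cells in expanded clonotypes than CON libraries at both days. At day 5 the share was 8.15% ± 5.61 in CON and 3.07% ± 0.959 in KO, and at day 14 it was 57.1% ± 1.66 in CON and 49.5% ± 4.21 in KO (SD, n = 2 each). The day 5 groups were barely apart, with 4.19% in CON and 3.75% in KO for replicate 1. With chains of 2 or more UMIs they overlapped (3.17% and 3.97% in the same libraries). They also overlapped with the authors' clonotype ID and with TRB alone. They did not without possible doublets, without subsampling or without iNKT-type cells, so their separation depended on the setting. Over both days the KO minus CON difference was -6.35 points, with p = 0.0556 in the exact permutation test, the smallest the design allows, and 0.194 after adjustment over 7 measures. It was -5.08 points at day 5 and -7.62 at day 14, each with an exact p of 0.333, the smallest for 2 against 2. The change of the KO effect between days was -2.54 points (exact p = 0.778), and it turned to 1.42 without the day 5 CON library of replicate 1 and to 0.435 without the day 14 KO library of replicate 2. It was -6.15 over all cells without subsampling and -1.35 without iNKT-type cells. The day 5 difference was -1.12 without the CON library of replicate 2 and -9.05 without that of replicate 1. The day 14 difference was -4.65 without the KO library of replicate 2 and -12.4 over all cells without subsampling. The 10 most frequent clonotypes held 5.88 points less in KO over both days (difference -5.88, exact p = 0.0556, adjusted 0.194). The chance that 2 cells share a clonotype differed by -0.321 points (exact p = 0.389), by -0.652 with the authors' clonotype ID, by -0.556 with TRB alone, by 0.0707 without the day 14 CON library of replicate 2, by -0.713 without that of replicate 1 and by -0.176 without the day 14 KO library of replicate 2. At day 14 it differed by -0.571, by -1.23 with the authors' clonotype ID and by -1.05 with TRB alone. It turned to 0.213 without the day 14 CON library of replicate 2, and ranged from -1.35 to 0.213 over the libraries left out.

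The use of V and J segments did not differ past the threshold between KO and CON at either day. At day 5 edgeR called 0 of 98 segments, 0 had an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to TRAJ5, TRAV9-1, TRAJ40, TRAV9-2, TRAJ33, TRBV13-3, TRBV10 and TRBV29. TRAJ5 had a log2 fold change of -3.70 ± 1.66 (SE), and -6.58 without the day 5 KO library of replicate 1 or -5.98 with chains of 2 or more UMIs. TRAV9-1 had one of -1.25 ± 0.63, and -0.44 without the day 5 CON library of replicate 2 or -0.49 with each clonotype counted once. At day 14 edgeR called 0, 11 had an unadjusted p under 0.05, and DESeq2 called 0. These fits took 1 spread for both days. Yet shares varied more at day 14 for most lists, such as the iNKT V beta list (SD 1.05 at day 5, 7.44 at day 14). The exceptions were the J-proximal V alpha list and the iNKT-type and MAIT-type alpha chains. The SE and p of day 14 may thus be too small and those of day 5 too large. Fits of each day's libraries alone, added after seeing the data, called 0 segments at either day. TRAJ18 had a log2 fold change of 0.94 ± 0.27, TRAJ34 2.05 ± 0.60, TRBV20 2.55 ± 0.78, TRAJ47 1.91 ± 0.64, TRAJ5 3.27 ± 1.10, TRAV13-3 5.31 ± 1.84, TRAV7-5 -2.54 ± 0.94 and TRBV19 -1.50 ± 0.58. The edgeR adjusted p of the first 6 was 0.288. Several of these rest on a clonotype of a single library: TRAV13-3 was 13.0% of TRA cells in the day 14 KO library of replicate 2 and absent from the other, and TRBV20 was 13.9% of TRB cells in the KO library of replicate 1 and 2.21% in the other. With each clonotype counted once TRBV20 had a log2 fold change of -0.18, TRAJ18 0.21, TRAJ34 0.45, TRAV7-5 -0.23 and TRBV19 -0.68, and the other 3 were not tested. Without iNKT-type cells, an alternative added later, TRAJ18 had one of 2.18 at day 14, 0.96 over both days (against 0.48) and 2.55 in the interaction (against 0.86), and passed in none. Its interaction value of 0.86 ranged from 0.54 to 1.11 over the libraries left out. With TRAV copies kept apart TRAV7-5 was -0.70 at day 14 and -0.53 over both days. TRAV13-3 turned to -3.05 without the day 14 KO library of replicate 2 and moved to 8.12 without the day 14 CON library of replicate 1, and TRAV7-5 turned to 0.0293 without the day 14 CON library of replicate 2. TRBV20 moved to 0.71, TRAJ5 to 0.48 and TRAJ34 to 1.23 without the day 14 KO library of replicate 1, and TRBV19 to -0.43 without the day 14 CON library of replicate 1. Without the day 14 KO library of replicate 2, 5 segments passed at day 14, without that of replicate 1, 2 passed, and without the day 14 CON library of replicate 1, 1 passed.

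Over both days edgeR called 0 segments between KO and CON, 5 had an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to TRAV13-3 (log2 fold change 4.25 ± 1.52, SE), TRBV19 (-1.01 ± 0.42), TRBV12-2 (0.72 ± 0.31), TRBV17 (-1.44 ± 0.63), TRAV7-5 (-1.65 ± 0.73), TRAJ18 (0.48 ± 0.22), TRBV20 (1.43 ± 0.69) and TRAJ34 (1.10 ± 0.55). Single libraries carry several of these values. TRAV13-3 was 0.95 and TRAJ18 0.28 without the day 14 KO library of replicate 2, TRBV20 0.36 and TRAJ34 0.55 without that of replicate 1, TRAV7-5 -0.34 without the day 14 CON library of replicate 2, and TRBV17 -0.53 and TRBV19 -0.50 without that of replicate 1. With each clonotype counted once TRBV19 was -0.40, TRBV17 -0.66, TRAV7-5 -0.49, TRAJ18 0.07, TRBV20 -0.09 and TRAJ34 0.21. The interaction gave 0 edgeR calls, 4 segments with an unadjusted p under 0.05 and 0 DESeq2 calls. TRAJ5 had a log2 fold change of 6.97 ± 1.95 (SE) in the interaction, and 4.17 without the day 14 KO library of replicate 1. With the replicate block edgeR called it (6.70), as it did without the day 14 KO library of replicate 2 (7.86). The smallest p of the interaction belonged to TRAJ5, TRAJ27, TRAJ34, TRAJ18, TRBV20, TRAJ47, TRAV9-1 and TRBV5. None of the 11 lists passed in edgeR between genotypes at day 5, at day 14 or over both days, and 0, 1 and 0 lists had an unadjusted p under 0.05. The iNKT-type share was 27.7% ± 2.91 in CON and 29.9% ± 0.377 in KO at day 5, and 3.21% ± 0.0389 in CON and 4.79% ± 1.43 in KO at day 14 (SD, n = 2). Over both days its log2 fold change in KO was 0.30 ± 0.27 (SE, edgeR adjusted p = 0.749). At day 14 the V-distal J alpha list was nearest to the threshold, with 16.6% ± 1.31 in CON and 29.3% ± 12.3 in KO and an adjusted p of 0.150. Without the day 14 KO library of replicate 2 2 lists passed at day 14, that list among them, and 2 in the interaction, and with the replicate block that list passed at day 14 (log2 fold change 0.78). Its log2 fold change at day 14 was 0.82 with all libraries, 1.20 without the KO library of replicate 2, 0.32 without that of replicate 1 and 0.14 with each clonotype counted once, so the value rests largely on replicate 1. Of its 10 tested members none passed at day 14, with TRAJ5 at 3.27, TRAJ9 at -1.34 and TRAJ7 at 1.01. The Vbeta5 list passed at day 14 with each clonotype counted once, with a log2 fold change of 0.94, against 0.69 over all cells (TRBV12-2 0.99, TRBV12-1 0.58).

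Cells with 2 productive TRA chains made up 7.27% ± 1.16 of paired cells at day 5 and 14.75% ± 4.095 at day 14 (SD, n = 4 each, exact p = 0.0556). With each TRB clonotype counted once the shares were 7.43% ± 1.18 and 9.35% ± 1.76. The KO minus CON difference was -1.28 points (exact p = 0.5), -0.341 with cells thinned to 4 TRA UMIs, and it turned to 0.403 without the day 14 CON library of replicate 2 and to 0.399 without the day 14 KO library of replicate 1. The TRA CDR3 differed by -0.324 residues between day 14 and day 5 (exact p = 0.0556), but by -0.0139 without iNKT-type cells, and the TRB CDR3 differed by -0.122 residues (exact p = 0.111), or by -0.309 when averaged over cells (exact p = 0.0556). The TRB CDR3 hydropathy was -1.19 ± 0.0357 at day 5 and -1.08 ± 0.0238 at day 14 (exact p = 0.0556), and the difference of 0.105 was 0.0622 without iNKT-type cells (both removals were added after seeing the data) and changed sign when averaged over cells in place of clonotypes. Between genotypes the differences were 0.00426 residues for TRA, 0.00535 for TRB and 0.0124 for hydropathy, with exact p of 0.944, 1 and 0.556, and each changed sign without at least 1 of the libraries.

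TRB amino acid sequences were shared mostly between libraries of day 14. A pair of day 14 libraries shared 52.6 per 1e+06 possible pairs on average, with 6 to 13 sequences in common, against 3.97 for a pair of day 5 libraries and 3.85 across days. Pairs of the same day exceeded pairs of different days by 24.4 (exact p = 0.111, the smallest possible). That difference was 13.4 without the day 14 CON library of replicate 2, 15.1 and 16.1 without the day 14 KO libraries of replicates 1 and 2, and 8.93 for nucleotide sequences. Pairs of the same genotype differed from pairs of different genotype by -5.99 (exact p = 0.889), by -2.47 for nucleotide sequences and by 2.55 without the day 14 CON library of replicate 2.

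The most frequent clonotype held 12.5% ± 3.19 of paired cells at day 14 and 1.55% ± 0.919 at day 5 (SD, n = 4 each). At day 14 it paired TRAV14-1 and TRAJ24 with TRBV19 and the CDR3 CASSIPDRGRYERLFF in the CON library of replicate 1, at 8.24% (95% exact interval 6.74 to 9.95). In the KO library of replicate 1 it paired TRAV7-4 and TRAJ5 with TRBV20 and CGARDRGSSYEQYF, at 13.2% (10.3 to 16.5). In the libraries of replicate 2 it used TRBV13-1, TRBJ1-1 and the TRB CDR3 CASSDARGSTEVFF in both genotypes, with TRAV7-5 and TRAJ50 at 15.9% in CON (13.3 to 18.9) and with TRAV13-3 and TRAJ50 at 12.8% in KO (10.1 to 15.8). In that CON library the clonotype ranked 3 (34 cells, TRAV6-6 and TRAJ43) had the same TRB CDR3. Of cells with this TRB CDR3, 101 of 151 in CON and 53 of 86 in KO held a TRAV6-6 and TRAJ43 chain beside the TRAJ50 chain. Taking the chain with the most UMIs can thus split cells with 2 alpha chains over clonotypes, which lowers these shares. At day 5 the most frequent clonotype held 10 and 15 cells in the CON libraries and 3 cells in each KO library. These began with TRAV5-4 and TRBV19, TRAV9-1 and TRBV26, TRAV6-6 and TRBV1, and TRAV5-4 and TRBV13-3, in the order CON replicate 1, CON replicate 2, KO replicate 1 and KO replicate 2.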

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

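Alternatives said below to be added were chosen after the results were seen, and the others before. Of 488 alternatives for 33 comparison results 443 kept both direction and call, counts of calls to within a factor of 1.5, and of 793 for 42 single segments 728 kept both. Values compared by exact permutation had no call to lose, and could gain one only with labels permuted over all 8 libraries. For these values a kept call therefore says nothing, and only the direction was open to change. With each clonotype counted once TRBV20 turned from higher to lower in KO at day 14 (-0.18), over both days (-0.0924) and in the interaction (-0.20), 1 list passed at day 14 and 7 lists between days. Counting clonotypes once and leaving out iNKT-type cells (added after seeing the data, like the joint name below) gave TRBV20 -0.18, -0.0881 and -0.21, and 6 segments between days. Without iNKT-type cells 2 segments and 0 lists passed between days, TRBV31 at -1.86 and TRBV12-2+TRBV13-2 at -1.08, while TRBV13-2 (-1.77) and TRBJ1-3 (-1.25) kept their size and lost the call. The iNKT-type alpha chain could not pass in that alternative, which removed its cells. The day differences were then -0.0139 for TRA length and 0.0622 for hydropathy, and the TRA length difference between genotypes turned to -0.00380. With the replicate block 1 list passed at day 14 and 1 segment in the interaction, and 7 segments passed between days. Deviations of libraries with the same number did not go together (correlations -0.121 to 0.0696 over pairs of groups), so the numbers do not show a pairing. TMM factors gave 4 lists between days, and the joint name counted as TRBV13-2 gave 6. With labels permuted over all 8 libraries, an alternative added after seeing the data that ignores genotype, p was 0.0286 for the day differences in expanded share (47.7), top 10 share (28.9), chance of sharing (2.43), 2 TRA chains (7.47), TRA length (-0.324) and hydropathy (0.105). The mean over cells turned hydropathy between days to -0.0255. Between genotypes TRA length turned to -0.00977 with 2 or more UMIs, TRB length to -0.000102 without possible doublets, and 2 TRA chains to 0.127 with each TRB clonotype counted once (added).

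Leaving out each library gave 0 to 5 segments at day 14 between genotypes, 5 to 12 between days and 0 to 1 in the interaction, and 0 to 2, 2 to 4 and 0 to 2 lists. TRAV13-3 at day 14 ranged from -3.05 to 8.12 and TRAV7-5 from -3.43 to 0.0293. Between genotypes the ranges were -0.713 to 0.0707 for the chance of sharing over both days and -1.35 to 0.213 at day 14, -2.96 to 0.403 for 2 TRA chains, -0.0528 to 0.0613 for TRA length, -0.0327 to 0.0434 for TRB length, -0.00633 to 0.0312 for hydropathy and -11.0 to 2.55 for TRB sharing. The change of the expanded share's KO effect between days ranged from -6.51 to 1.42. Where a library left its group with 1 library, that library was assumed to vary like the others. The cause of these differences was not tested.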

Other observations

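The tests of the explanations below were chosen after the results were seen, except the counts over other splits of the libraries. Groups of related TRB chains seen in 3 or more libraries are described first, some of them picked after their values were seen. TRB chains were called neighbours when they had the same V and J segments, the same CDR3 length and at most 1 amino acid difference, among cells without an iNKT-type alpha chain. TRBV5 with TRBJ2-7, mostly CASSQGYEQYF, covered 191 cells in 5 libraries, of which 165 carried TRAV7-6 with TRAJ22. TRBV12-1 with TRBJ2-5 covered 186 cells with 11 CDR3 sequences, all of day 14, and paired with TRAV10 and TRAJ27 (73 cells), TRAV5-1 and TRAJ27 (62) or TRAV10 and TRAJ34 (32). TRBV20 with TRBJ2-7 covered 74 cells, of which 70 were in the day 14 KO library of replicate 1. TRBV3 with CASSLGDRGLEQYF was seen in 15 cells of all 4 day 14 libraries, each with TRAV9-1 and TRAJ23. The TRB chain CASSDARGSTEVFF, in 2 libraries and so outside these groups, was found in 151 cells of the CON library of replicate 2 and 86 cells of the KO library of replicate 2. Of these, 101 and 53 cells also held the alpha chain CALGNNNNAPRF beside another TRAJ50 alpha chain that differed between the libraries.

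Related TRB chains in different day 14 libraries were concentrated among TRB chains seen in 2 or more cells. These are called expanded here, whatever alpha chains the cells carried. Of 325 expanded TRB chains at day 14, 26.8% had a neighbour in another day 14 library (95% exact interval 22.0 to 31.9), against 7.21% of 1235 seen in 1 cell (5.83 to 8.79). At day 5 the shares were 3.45% of 58 and 4.45% of 1617. Carry-over between libraries is argued against as the only source, since 36.7% of 49 shared amino acid sequences had the same nucleotides in both libraries (23.4 to 51.7), and none of 21 barcodes seen in 2 libraries carried the same TRB. The 18 with the same nucleotides could still be carried over. A sequence counts among the 49 for each pair of libraries that share it, so the interval takes repeats as independent. Here iNKT-type cells were included. Of the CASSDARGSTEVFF chain none of 3 nucleotide sequences was in both libraries, but 1 of the 2 nucleotide sequences of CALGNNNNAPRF as first alpha chain was, so carry-over of that alpha chain is not excluded. Sequences that recombination makes often cannot be told apart from clonal growth by comparing expanded with single-cell TRB chains. A chain made often can arise in 2 cells with different alpha chains, and it then counts as expanded. The share with a neighbour was at least 3.32 times as high among expanded as among single-cell TRB chains in each day 14 library, with intervals that did not overlap. These intervals take chains as independent, but a pair of neighbours counts in both libraries and related chains form groups. The libraries are therefore not separate replicates of this difference. The size of a TRB chain was redefined after a first run as that of its largest set of cells with the same TRB nucleotides. A hypothesis that stays open is selection by a common ligand: 54.7% of 172 neighbouring pairs had the same TRAJ, 12.1 times the 4.51% of other pairs with the same TRBV, more than in any of 10000 redraws of alpha chains (permutation p = 0.0001, the smallest they can give). Pairs within a group are not independent, and outside the 3 groups with most pairs 45.3% of 95 pairs had the same TRAJ. The ligand is not known from these data.

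The fall of the iNKT-type share at day 14 was weighed against dilution by expanded clonotypes. With each clonotype counted once the share was 29.7% ± 1.51 at day 5 and 7.23% ± 0.906 at day 14 (SD, n = 4 each), so day 14 stood at 24.4% of day 5 and dilution can be only a part. Capture of TRA chains was not poorer at day 14, where the share of cells with a TRA chain was higher by 6.24 points. The time since tumour implantation stays open, as does any difference in preparation between the days, which the labels do not describe. The number of iNKT-type cells in the tissue cannot be read from shares.

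The smaller expanded share in KO libraries was weighed in the same way. A different share of iNKT-type cells is argued against, since the difference was -7.06 points without them, with no overlap within either day. A difference in chain capture cannot be told apart, since with TRB alone the difference was -5.54 points but the day 5 groups overlapped. A single CON library could account for day 5, where leaving it out gave -1.12 points against a gap of 1.36 between the KO libraries. At day 14 the difference nearest to 0 with 1 CON library left out was -6.45 points, against a gap of 5.96 between the KO libraries. This leaves that explanation open. Without the KO library of replicate 2 the day 14 difference was -4.65 points, smaller in size than that gap. The Matr3 genotype stays among the open explanations.

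Over 34 splits of the 8 libraries into 4 and 4, the time contrast called 10 segments and no other split called more than 1. Thus 1 of 34 splits gave as many, the smallest share that this count can give. This argues against chance assignment but does not exclude it. Every other split mixed the days, so the difference between days added to the spread within its sides. For the lists the time contrast called 2, the highest other split 1, and 1 of 34 splits gave as many. For genotype over both days 0 segments and 0 lists were called and the highest other split called 1 of each, and since a count of 0 is met by all 34 splits whatever the data, this says nothing about chance.

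Barcodes that were not called cells held mainly one kind of contig. A non-productive TRBV26 contig with the CDR3 CKGRFCEV was found in 60.3% to 88.9% of these barcodes per library. A TRBV26 contig with this CDR3 was found in 0 cell barcodes, and other TRBV26 contigs were not counted. The counts were 1250 and 1108 in CON and 813 and 1717 in KO at day 5, and 1121 and 3056 in CON and 3219 and 1966 in KO at day 14.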
